A study of Homo sapiens with 24 samples.

How the data were processed

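RNA of T-HESC cells was sequenced from 4 groups of 3 libraries, treated with siRNA labelled GLI1, HRK1, PRRX2 or Ctrl8, each library being run on 2 lanes (24 samples in all). Per the labels' protocols, knockdowns were done as separate biological replicates, libraries were stranded total RNA with ribosomal depletion, and only samples past a knockdown threshold by quantitative PCR were sequenced. Per the submitters' processing notes, HISAT2 2.1.0, StringTie 1.3.6, edgeR, limma and DESeq2 2.11.40.6 were used with the build hg38, with no role given for each. The annotation release, the read counting and the strand setting are not given in the sources used here.

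The deposited files are 3 tables of the authors' own comparisons, with 1 row per Ensembl transcript (100454) and no value per library. Per the file headers, the deposited signal is a base mean, the mean over the libraries of counts divided by the size factors of DESeq2, as the authors ran it. Transcripts seen as a single count took 6 levels of base mean in each table, so that 6 libraries entered it and the 2 lanes of a library had been merged by the authors. The implied size factors, relative to 1, ran from 0.955 to 1.09 for GLI1, 0.974 to 1.06 for HRK1 and 0.948 to 1.04 for PRRX2. Per the file headers, the authors also gave a log2 fold change with its standard error. The deposited score is the Wald statistic, equal to the log2 fold change over its standard error. The deposited p-value is the two-sided Wald p of the authors' DESeq2 run, and beside it stands their Benjamini-Hochberg adjusted p, which is blank where they filtered. A blank was kept as blank. Depth per library was unknown, and precision is described by the standard errors.

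The headers do not give the direction of the fold change. Positive was read as siRNA over control, since PRRX2 was negative in its own comparison and since the implied control arms then matched between tables. The SD of their log2 difference was 0.258, 0.261 and 0.262 for the pairs, against 1.25, 1.25 and 1.27 if one table were inverted. Arm means were implied from the base mean and the fold change, assuming 3 libraries in each arm. Transcripts were named through GENCODE 29, which matched 83066 of 100454 identifiers (82.7%). Among transcripts with a base mean of at least 10, 5.07%, 5.04% and 5.11% had no name, holding 1.69%, 1.73% and 1.67% of the summed base mean.

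Calls in the authors' tables were read as deposited at an adjusted p under 0.05. Since these are transcripts, implied arm means were also summed over the transcripts of each gene (sums with a mean of at least 50), with standard errors by the delta method that take transcripts as independent, a two-sided Wald test and Benjamini-Hochberg adjustment. This gene sum was chosen after seeing the data. Where 1 arm mean was under 1, the floor of 3 counts over the 3 libraries of an arm, the fold is given as a lower bound against that floor, and where both were, no fold is given. Simulated data over 11128 genes took control means averaged, and errors as the median, over the 3 comparisons. There 53.3% of 200 genes changed by 1 on the log2 scale and 70.9% of those changed by 2 were recovered. Of genes that only switched isoform 1.3% and 1.5% were called, and 9.2 and 12.2 unchanged genes were called per draw. Genes drawn to switch were not required to have several transcripts, so some may have been unable to switch. Transcripts without a name entered neither the gene sums nor the simulated switches. A switch to or from such a transcript could therefore pass as a change of the whole gene, which the simulation cannot show.

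Fixed gene lists (37), which included markers of other cell types and of RNA quality, were written before the data were examined. They were tested with cameraPR in limma 3.58.1 on R 4.3.3, two-sided, on the Wald statistic of the most abundant transcript of each gene with a base mean of at least 10, for lists with at least 5 measured members. The preset inter-gene correlation was 0.01, with 0.05 as an alternative, and adjustment was by Benjamini-Hochberg over 34, 35 and 34 lists for GLI1, HRK1 and PRRX2. In simulated data over 13153 genes a shift of 0.8 in a list was recovered in 94% of cases, with false calls in 0.129%. The simulated statistics were independent between genes, so this rate of false calls does not cover lists of correlated genes. Differences between siRNAs were tested by z, the difference of the log2 changes over the root of the summed squared errors, two-sided, with Benjamini-Hochberg adjustment. Lists were tested on that z with cameraPR. Overlaps were set beside independent lists and 100 simulated draws with the same controls and no change.

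The genes named in the text follow a rule set before the data were examined. It took the targeted genes, the 10 lowest and 10 highest called transcripts with a base mean of at least 50, up to 4 called members of lists that passed or had at least 3 calls, the 5 genes most different in each pair, and the 5 highest and 5 lowest of those called in all 3 comparisons. After the data were seen, the 12 lowest and 12 highest called gene sums with a mean of at least 100 and a transcript called in the same direction were added, since the largest transcript changes were isoform switches. Genes without a symbol are not named. Further members of lists that did not pass the test alone, and DICER1's gene sum, are given as values.

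For the closing section, 3' UTRs of at least 50 bases in 9386 genes with a gene sum of at least 100 were scanned for 7-mers carried by at least 50 genes, and each z of carriers against other genes, with trends in 3' UTR length and GC content removed, was set against 100 shuffles. Words with at least 5 consecutive bases in common with the lowest were counted, the lowest itself included. In simulated data a planted 7-mer with a log2 change of −0.3 was recovered as the lowest in 100% of 50 draws. Alternatives covered thresholds, filters, centring, the handling of lanes, the correlation between genes, ranks, single members, gene sums, seed matches and GC content. Leaving out replicates, other count tests and a replicate block could not be run, since no per-library values were at hand. Software was Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.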

Results

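RNA was measured in T-HESC cells, a human line of endometrial stromal fibroblasts immortalised with telomerase (hTERT), which stand for the connective tissue cells of the uterine lining. The cells were transfected with 50 nM of an siRNA carrying the label GLI1, HRK1 or PRRX2, or with a non-targeting control siRNA carrying the label Ctrl8, and RNA was taken 48 h later. The 24 samples were 12 libraries, 3 biological replicates per group, each run on 2 sequencing lanes. The libraries were made from ribosome-depleted total RNA and read in single reads of 50 bases. The question of each comparison, as far as the series describes it, was which transcripts change when a transcription factor is lowered. The deposited values were 3 tables of 100454 transcripts, each comparing 1 siRNA with Ctrl8, with no value per library. The depth of each library was therefore unknown. Base means, the mean normalised counts over the libraries of a comparison, summed to 22631892 for GLI1, 22497853 for HRK1 and 22622305 for PRRX2. In the authors' deposited table, the median SE of a log2 change for base means of at least 100 was 0.36 for GLI1, 0.40 for HRK1 and 0.38 for PRRX2. Between base means of 10 and 100 these medians were 1.21, 1.23 and 1.21. Transcript values were also summed here to genes, and "gene sum" names that quantity throughout. Only transcripts with a name were summed, so a switch to or from an unnamed transcript could pass as a change of the gene.

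The targeted genes were examined first. PRRX2, a paired-type homeobox transcription factor of mesenchyme (chromosome 9, 129665641 to 129722674 in hg38), fell under PRRX2 siRNA from an implied mean of 257 to 32.0 normalised counts. Its log2 change was −3.01 with an SE of 0.79 (gene-sum Wald test, Benjamini-Hochberg adjusted p = 0.00904). Under GLI1 siRNA the PRRX2 gene sum had a log2 value of −0.28 (SE 0.17), and under HRK1 siRNA −0.15 (SE 0.23). GLI1, a zinc finger transcription factor of Hedgehog signalling (chromosome 12, 57460135 to 57472262), had 124.5 normalised counts with Ctrl8 and 46.0 with GLI1 siRNA, a percent change of −63.1. This log2 value of −1.44 (SE 0.74) did not pass the gene-sum Wald test (Benjamini-Hochberg adjusted p = 0.752). GLI1 had log2 values of 0.32 (SE 0.55) under HRK1 siRNA and −0.95 (SE 0.81) under PRRX2 siRNA, neither past the test. No transcript carried the current symbol HRK1. Read as HRK, a BH3-only regulator of apoptosis, the target had implied means of 0.882 with Ctrl8 and 0.727 with HRK1 siRNA in the authors' deposited table, both under the floor of 3 counts over an arm. The HRK1 knockdown could not be checked, since the gene meant by the label is open and HRK, the only reading reported here, lay under the floor. The label is used below as a name for the siRNA.

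TOMM34, a cochaperone of mitochondrial protein import, was the lowest of the called gene sums with a mean of at least 100 under GLI1 siRNA and fell from 578 to 103 normalised counts (log2 −2.48, SE 0.16; gene-sum Wald test, Benjamini-Hochberg adjusted p = 2.01e-47). PRDX3, the peroxiredoxin of mitochondria, fell by 1.86 on the log2 scale (SE 0.25), and SOD2, the mitochondrial superoxide dismutase, fell by 1.47 (SE 0.29), from 2106 to 759 normalised counts. SFXN3, a mitochondrial amino acid carrier, fell by 1.84 (SE 0.22). DNMT3B, a de novo DNA methyltransferase, rose by 1.60 (SE 0.34), from 84.9 to 258 normalised counts, and TXNDC5, a disulfide isomerase of the endoplasmic reticulum, rose by 1.31 (SE 0.17).

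CSF2RB, the common beta subunit of the GM-CSF, IL-3 and IL-5 receptors, fell by 2.37 (SE 0.45), ARL2BP, a partner of the small GTPase ARL2, fell by 1.79 (SE 0.19), and PRKAR2A, a regulatory subunit of protein kinase A, fell by 1.54 (SE 0.17). The receptors S1PR2 for sphingosine-1-phosphate and SSTR1 for somatostatin fell, with log2 values of −1.40 (SE 0.28) and −1.38 (SE 0.27). SELENOF, a selenoprotein of the endoplasmic reticulum, fell by 1.65 (SE 0.39), NBDY, a microprotein of P-bodies, fell by 1.62 (SE 0.21), and MBLAC2 fell by 1.51 (SE 0.32). Of the 12 lowest of these gene sums under GLI1 siRNA, 9 held the 7-mer GGTCCTG in their 3' UTR, which 1042 of 9386 genes searched held, and 0 of the 9 highest that could be searched. This word, like those given below for HRK1 and PRRX2 siRNA, was picked from these same gene sums, so such counts are no separate support. Among the highest, the protein kinase A inhibitor PKIA rose by 1.17 (SE 0.34), the chromatin protein HMGA2 by 0.92 (SE 0.23), C2CD2 by 0.92 (SE 0.23) and MIR23AHG, the host gene of the miR-23a cluster, by 0.85 (SE 0.11). RNF38, a ubiquitin ligase, rose by 0.76 (SE 0.14), the integrin subunit ITGA3 by 0.74 (SE 0.22), the G1 kinase CDK6 by 0.66 (SE 0.15) and SOWAHC by 0.62 (SE 0.16). GOLGA8B rose by 0.71 (SE 0.19) but belongs to a family of near-identical copies, and its value is uncertain. Over all genes 148 of 11119 gene sums changed, 39 higher and 109 lower, and 753 had an unadjusted p under 0.05.

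Of the fixed lists of cell division genes, the replication-dependent histones were higher under GLI1 siRNA at both preset correlations. All 43 measured replication-dependent histone genes had a log2 value above 0, with a median of 0.37 (cameraPR adjusted p = 2.4e-05), although 0 of them passed over all genes tested and 0 passed adjusted over the list alone. H2BC18, H1-5 and H4C11 had values of 0.48 (SE 0.29), 0.48 (SE 0.33) and 0.44 (SE 0.34) in the authors' deposited table. Many histone genes are near-identical copies, so that counts could be split among them. The mitosis list had 32 of 41 members above 0 and a median of 0.27 (cameraPR adjusted p = 0.00024, and adjusted p = 0.051 with a preset correlation of 0.05), with 0 members past the test over all genes tested and 0 adjusted over the list alone. The DNA replication list had a median of 0.31 (cameraPR adjusted p = 0.0048, and adjusted p = 0.19 with a preset correlation of 0.05). Of its 43 members 2 rose over all genes tested, and 2 adjusted over the list alone: MCM4, a subunit of the replicative helicase, by 0.47 (SE 0.13), and E2F8, an atypical E2F repressor, by 0.67 (SE 0.20) in the authors' deposited table. Their gene sums, 0.20 (SE 0.19) and 0.65 (SE 0.20), did not pass, and over all transcripts the list did not pass either (cameraPR adjusted p = 0.11). A correlation between genes could not be estimated for any list in the 3 comparisons, since no per-library values were at hand, and preset values of 0.01 and 0.05 were used.

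The remaining fixed lists did not pass as planned under GLI1 siRNA. By gene sums, however, the integrated stress response list, described below, was higher (cameraPR adjusted p = 0.013, against 0.15 as planned). The contractile list was lower by gene sums (cameraPR adjusted p = 0.034, against 0.15 as planned). The Hedgehog pathway list had 18 measured members with a median of −0.08 and 0 called over all genes tested (cameraPR adjusted p = 0.74), and 0 adjusted over the list alone. In the hypoxia and glycolysis list (cameraPR adjusted p = 0.87), 2 of 29 members rose and 2 fell over all genes tested, with the same counts adjusted over the list alone. In the authors' deposited table the glucose transporter SLC2A3 rose by 0.61 (SE 0.10) and ANGPTL4, an inhibitor of lipoprotein lipase, by 2.51 (SE 0.51), while the carbonic anhydrase CA12 fell by 0.76 (SE 0.21). The fourth, an ENO2 transcript of the neuronal enolase gene, went from an implied mean of 145 to under the floor in the authors' deposited table, at least 145-fold lower, while the ENO2 gene sum was at −0.20. The markers of stromal fibroblasts (median −0.12, cameraPR adjusted p = 0.74), pericytes and smooth muscle (0.05, 0.97) and the mitochondrially encoded transcripts (−0.07, 0.97) did not pass.

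In the authors' deposited table, 295 transcripts rose and 327 fell under GLI1 siRNA at a DESeq2 adjusted p under 0.05, and 2348 had an unadjusted p under 0.05. The largest of these were single isoforms whose gene sums did not pass the test. An RPL37A transcript of a large ribosomal subunit protein went from 8126 implied normalised counts to under the floor in the authors' deposited table, at least 8126-fold lower, while the RPL37A gene sum was at −0.02 (SE 0.15). Transcripts of WDR6, FOCAD, ZNF532, CNOT6, SLC12A4, MTMR1, ARL13B, GANAB and ATG4C were the next lowest, and those of PUM2, FOCAD, CNOT6, STAU1, TDP1, PPM1F, MMS19, RBMXL1, BORA and RPLP0 were the highest. FOCAD and CNOT6 stood in both groups through different isoforms. Of 489 genes with a called transcript and a gene sum, 217 had a gene sum that moved by less than 1.2-fold (44.4%).

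**Figure D1:**
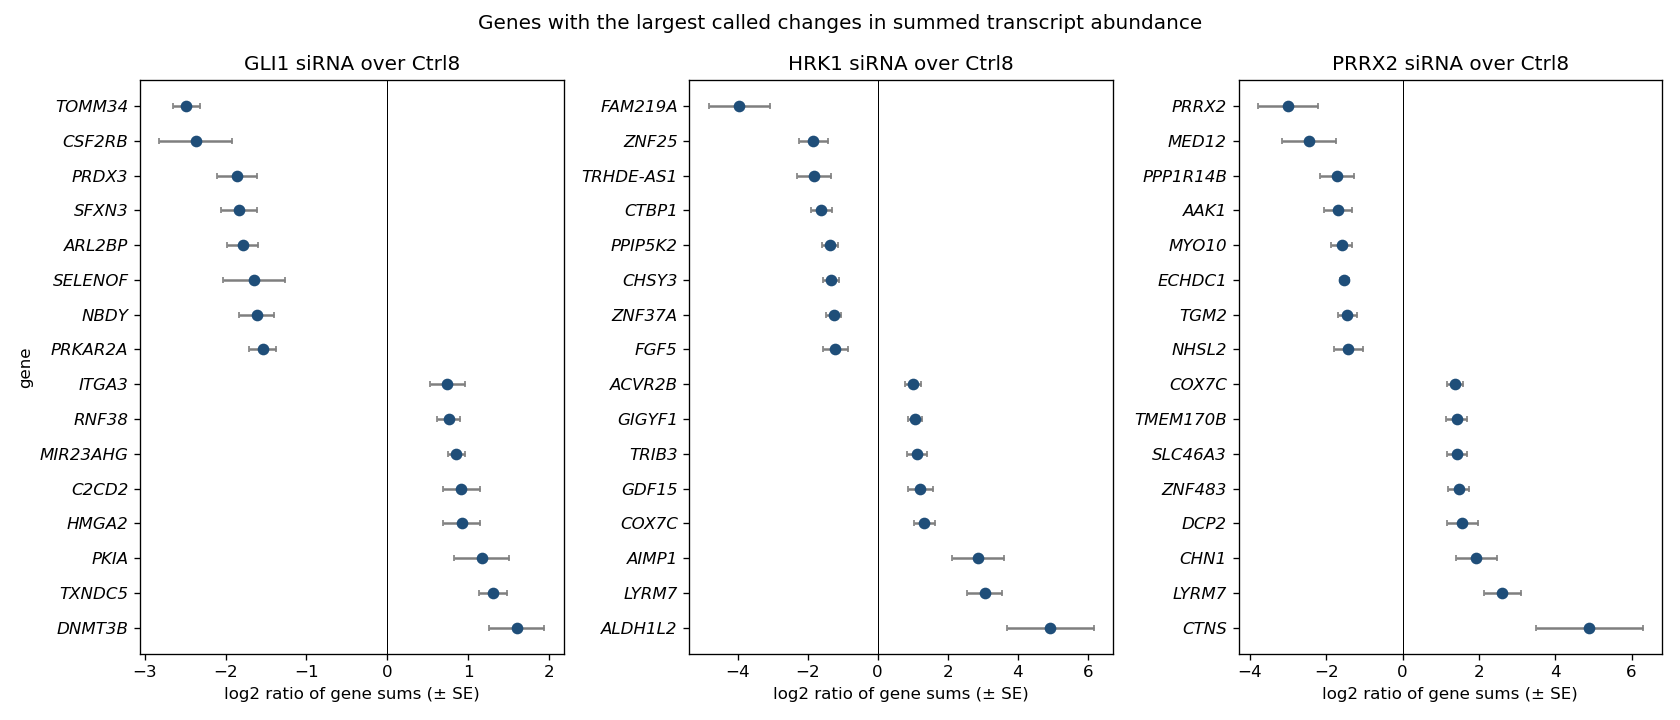
Log2 ratio of gene sums (horizontal axis, siRNA over Ctrl8) for the genes with the lowest and highest called gene sums in each comparison (vertical axis), 8 each way. Points are ratios and bars are ± 1 SE. Genes without a symbol and the overlapping genes NME1, NME1-NME2 and AC008878.3 are left out. TOMM34 lies at −2.48 under GLI1 siRNA, ALDH1L2 at 4.93 under HRK1 siRNA and PRRX2 at −3.01 under PRRX2 siRNA.

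Under HRK1 siRNA, genes of the integrated stress response, which ATF4 drives when translation initiation is held back, rose. Of 32 measured members 7 rose over all genes tested and 9 adjusted over the list alone, with a median of 0.42 (cameraPR adjusted p = 9.9e-11). ALDH1L2, a mitochondrial folate enzyme, rose from 67.6 to 2064 normalised counts (log2 4.93, SE 1.23; gene-sum Wald test, Benjamini-Hochberg adjusted p = 0.00755). TRIB3, a pseudokinase, rose by 1.13 (SE 0.28), SESN2, a leucine-sensing inhibitor of mTORC1, by 0.91 (SE 0.20) and the transcription factor CEBPB by 0.74 (SE 0.12). DNA replication and mitosis genes fell as lists.

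The lowest called gene sums with a mean of at least 100 under HRK1 siRNA were spread over many functions. FAM219A fell by 3.95 (SE 0.87; gene-sum Wald test, Benjamini-Hochberg adjusted p = 0.00105). ZNF25 and ZNF37A, zinc finger proteins, fell, with log2 values of −1.83 (SE 0.42) and −1.26 (SE 0.22), the non-coding RNA TRHDE-AS1 fell by 1.82 (SE 0.49) and the transcriptional corepressor CTBP1 fell by 1.61 (SE 0.30). PPIP5K2, an inositol pyrophosphate kinase, fell by 1.36 (SE 0.23), the chondroitin synthase CHSY3 fell by 1.33 (SE 0.22), the fibroblast growth factor FGF5 fell by 1.21 (SE 0.36) and the cargo receptor LMAN1 fell by 1.19 (SE 0.20). UBE2J1, a ubiquitin-conjugating enzyme of the endoplasmic reticulum, fell by 1.15 (SE 0.22) and the initiation factor EIF1AX fell by 1.12 (SE 0.25). The 7-mer GAAGTCA stood in the 3' UTR of 9 of the 11 lowest genes that could be searched, in 1 of the 7 highest, and in 1222 of 9386 genes in all. NME1 fell by 1.33 (SE 0.39) while the overlapping readthrough gene NME1-NME2 went from 2.23 to 2511 normalised counts, and both are uncertain.

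Among the highest gene sums under HRK1 siRNA, LYRM7, an assembly factor of respiratory complex III, rose by 3.06 (SE 0.50), AIMP1, a scaffold of the multisynthetase complex, by 2.87 (SE 0.74) and the cytochrome oxidase subunit COX7C by 1.34 (SE 0.29). COX7C has processed pseudogenes, and its value is uncertain. The stress-induced cytokine GDF15 rose by 1.22 (SE 0.35), the translational repressor GIGYF1 by 1.07 (SE 0.21), the activin receptor ACVR2B by 1.01 (SE 0.24), the galactosyltransferase B3GALT1 by 1.00 (SE 0.22) and SH3TC1 by 0.97 (SE 0.27). Over all genes 185 of 11151 gene sums changed, 42 higher and 143 lower, and 826 had an unadjusted p under 0.05.

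The further called members of the stress response list were PPP1R15A, MTHFD2 and GARS1. PPP1R15A, which recruits phosphatase to eIF2alpha, rose by 0.42 (SE 0.10), the folate enzyme MTHFD2 by 0.39 (SE 0.10) and the glycyl-tRNA synthetase GARS1 by 0.32 (SE 0.09) in the authors' deposited table, while the GARS1 gene sum, 0.35 (SE 0.11), did not pass. The DNA replication list had 40 of 44 members below 0 and a median of −0.52 (cameraPR adjusted p = 9.9e-07). MCM6, a subunit of the replicative helicase, fell by 0.55 (SE 0.13) and the checkpoint adaptor CLSPN fell by 1.07 (SE 0.30) in the authors' deposited table, the 2 members past the test over all genes tested, against 6 adjusted over the list alone. The mitosis list had 38 of 42 members below 0 and a median of −0.38 (cameraPR adjusted p = 1.3e-05), with 0 called over all genes tested and 0 adjusted over the list alone. The replication-dependent histones, in contrast, had a median of −0.04 over 43 members and did not pass (cameraPR adjusted p = 0.63).

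Of the NRF2 target genes, which answer oxidative stress, 21 of 22 were above 0 under HRK1 siRNA with a median of 0.27 (cameraPR adjusted p = 6.6e-05). Only the aldo-keto reductase AKR1C2 rose over all genes tested, by 1.21 (SE 0.37) in the authors' deposited table but not by gene sum, and 2 members did so adjusted over the list alone. Among immediate early genes 4 of 29 rose and 1 fell over all genes tested, against 5 and 1 adjusted over the list alone (cameraPR adjusted p = 0.0044, and adjusted p = 0.075 with a preset correlation of 0.05). The transcription factors JUNB and KLF4 rose by 0.84 (SE 0.22) and 0.73 (SE 0.21) in the authors' deposited table, as did the early response genes IER2 and IER3, while SPRED1, an inhibitor of the Ras pathway, fell by 0.79 (SE 0.14). In the NF-kB list (cameraPR adjusted p = 0.0044, but adjusted p = 0.083 by gene sums, 0.072 by ranks of the statistic and 0.23 over all transcripts) 2 of 16 members rose over all genes tested, the chemokine CXCL8 by 1.65 (SE 0.27) and TNFAIP2 by 0.84 (SE 0.14) in the authors' deposited table, while the TNFAIP2 gene sum, 0.43 (SE 0.41), did not pass. Adjusted over the list alone, 3 of its members were higher and 1 was lower, and the list did not pass without its strongest member (cameraPR adjusted p = 0.11). The p53 target list had 2 members higher over all genes tested, SESN2 and GDF15, and 3 adjusted over the list alone (cameraPR adjusted p = 0.0498, and adjusted p = 0.23 with a preset correlation of 0.05).

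Epithelial markers also passed under HRK1 siRNA, with 5 of 23 measured and all 5 above 0 (cameraPR adjusted p = 0.0025). The keratin KRT19 rose by 0.44 (SE 0.09) in the authors' deposited table, the only call over all genes tested and adjusted over the list alone. Mitochondrially encoded transcripts (median 0.35, cameraPR adjusted p = 0.18), abundant non-coding RNAs (0.34, 0.067), cytosolic ribosomal proteins (0.09, 0.29), stromal fibroblast markers (−0.09, 0.47) and pericyte and smooth muscle markers (−0.10, 0.57) did not pass. The abundant non-coding RNAs, a sign of RNA quality, were however higher by ranks of the statistic (cameraPR adjusted p = 0.0084) and by gene sums (cameraPR adjusted p = 0.0072), the ribosomal proteins by gene sums (cameraPR adjusted p = 0.031) and the mitochondrially encoded transcripts by ranks of gene sums (cameraPR adjusted p = 0.042), beside the stress response and NRF2 genes. In all 3 comparisons at most 2 endothelial and at most 1 leukocyte markers were measured, too few for a test.

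In the authors' deposited table, 275 transcripts rose and 364 fell under HRK1 siRNA at a DESeq2 adjusted p under 0.05, and 2399 had an unadjusted p under 0.05. The lowest, an SNX14 transcript, went from an implied mean of 2015 to under the floor in the authors' deposited table, at least 2015-fold lower, while the SNX14 gene sum was at −0.01 (SE 0.51). The next lowest belonged to MAP2K4, CD99, CNOT6, PTGES3, OPA1, CCDC43, MTMR4, TMEM222 and NAXD. The highest belonged to CD99, GNAS, NME1-NME2, CNOT6, MATR3, PPM1F, CLIP1, IARS1 and ANKRD46. Of 524 genes with a called transcript and a gene sum, 221 had a gene sum that moved by less than 1.2-fold (42.2%).

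Under PRRX2 siRNA, cholesterol synthesis genes rose as a list, while contractile and immediate early genes fell as lists. The contractile list did not differ past the test between PRRX2 and GLI1 or HRK1 siRNA (cameraPR on the z of the difference, adjusted p = 0.19 and 0.51). By gene sums it was also lower under GLI1 and HRK1 siRNA (cameraPR adjusted p = 0.034 and 0.028), though not as planned (0.15 and 0.074). Extracellular matrix and matrix protease genes were lower as lists too, but not with a preset correlation of 0.05 (cameraPR adjusted p = 0.13 and adjusted p = 0.092). Over all transcripts the contractile and immediate early lists did not pass (cameraPR adjusted p = 0.061 and 0.068), while the matrix and protease lists did (0.0011 and 0.043). HMGCR, the rate-limiting enzyme of cholesterol synthesis, rose from 4514 to 6873 normalised counts (log2 0.61, SE 0.13; gene-sum Wald test, Benjamini-Hochberg adjusted p = 0.000619). The sterol carrier STARD4 rose by 0.51 (SE 0.11) and the thiolase ACAT2 by 0.49 (SE 0.11). The elastin crosslinking enzyme LOXL1 fell from 1690 to 942 normalised counts (log2 −0.84, SE 0.20), and TGM2, a crosslinking transglutaminase, fell by 1.45 (SE 0.25), from 314 to 115 normalised counts.

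Besides PRRX2, the lowest called gene sums with a mean of at least 100 under PRRX2 siRNA were in genes of several kinds. MED12, a subunit of the Mediator kinase module, fell by 2.45 (SE 0.71), the phosphatase inhibitor PPP1R14B fell by 1.72 (SE 0.44), the endocytic kinase AAK1 fell by 1.70 (SE 0.36) and the filopodial motor MYO10 fell by 1.60 (SE 0.27). ECHDC1, ethylmalonyl-CoA decarboxylase, fell from 1873 to 649 normalised counts (log2 −1.53, SE 0.12; gene-sum Wald test, Benjamini-Hochberg adjusted p = 2.64e-34). NHSL2 fell by 1.43 (SE 0.38), the nuclear receptor coactivator NCOA6 fell by 1.39 (SE 0.40), the small GTPase RAB15 fell by 1.39 (SE 0.26) and SIPA1L3 fell by 1.36 (SE 0.27). Of the 12 lowest of these gene sums 5 held the 7-mer AACAGCA in their 3' UTR, as did 3 of the 8 highest that could be searched, against 1459 of 9386 genes in all. AC008878.3 fell by 4.09 (SE 0.46) while a transcript of the overlapping ARHGEF18 gene rose, and both are uncertain.

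Among the highest gene sums under PRRX2 siRNA, CTNS, the lysosomal cystine transporter, went from 6.81 to 203 normalised counts (log2 4.90, SE 1.40). LYRM7 rose by 2.62 (SE 0.48), the Rac GTPase-activating protein CHN1 by 1.94 (SE 0.54), the decapping enzyme DCP2 by 1.57 (SE 0.41) and ZNF483 by 1.48 (SE 0.27). SLC46A3, a lysosomal transporter, rose by 1.43 (SE 0.27), TMEM170B by 1.42 (SE 0.27), COX7C by 1.37 (SE 0.21), ACVR2B by 1.24 (SE 0.27), SCML2 by 1.23 (SE 0.23) and TXNDC5 by 1.16 (SE 0.17). Over all genes 320 of 11176 gene sums changed, 153 higher and 167 lower, and 1177 had an unadjusted p under 0.05.

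The cholesterol synthesis list had 4 of 27 members higher over all genes tested, and 4 adjusted over the list alone, with a median of 0.34 (cameraPR adjusted p = 0.00047). Besides HMGCR, STARD4 and ACAT2, a transcript of lanosterol synthase, LSS, rose by 2.82 (SE 0.81) in the authors' deposited table, while the LSS gene sum, 1.16 (SE 1.06), did not pass. The contractile list had 23 of 25 members below 0 and a median of −0.36 (cameraPR adjusted p = 0.0017). Only PDLIM7, an actin-associated scaffold, fell over all genes tested and adjusted over the list alone, with a log2 value of −0.46 (SE 0.12) in the authors' deposited table, and its gene sum, −0.37 (SE 0.14), did not pass. The extracellular matrix list had 41 of 48 members below 0 and a median of −0.30 (cameraPR adjusted p = 0.0044, and adjusted p = 0.13 with a preset correlation of 0.05), with LOXL1 the only call over all genes tested and adjusted over the list alone. In the same list fibronectin, FN1, had a gene-sum value of −0.37 (SE 0.18) and collagen COL3A1 one of −0.02 (SE 0.37), neither past the test.

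Matrix proteases and their inhibitors had 21 of 25 members below 0 under PRRX2 siRNA and 4 lower both over all genes tested and adjusted over the list alone (cameraPR adjusted p = 0.0067, and adjusted p = 0.092 with a preset correlation of 0.05). The aggrecanases ADAMTS4 and ADAMTS1 fell, with log2 values of −0.80 (SE 0.19) and −0.40 (SE 0.10) in the authors' deposited table. The metalloproteinase inhibitors TIMP1 and TIMP3 fell too, with log2 values of −0.43 (SE 0.12) and −0.71 (SE 0.22) in the authors' deposited table. Immediate early genes had 3 of 29 lower over all genes tested and 6 adjusted over the list alone (cameraPR adjusted p = 0.0017). These were SPRY4, a feedback inhibitor of receptor kinase signalling, at −0.98 (SE 0.26), KLF2 at −0.93 (SE 0.27) and IER2 at −0.40 (SE 0.11) in the authors' deposited table, and the SPRY4 gene sum did not pass. The insulin-like growth factor list had 2 of 15 lower over all genes tested and 3 adjusted over the list alone (cameraPR adjusted p = 0.0040), with the stanniocalcins STC1 at −2.06 (SE 0.63) and STC2 at −0.47 (SE 0.15) in the authors' deposited table.

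The Hedgehog list had a median of −0.38 over 19 members under PRRX2 siRNA (cameraPR adjusted p = 0.041, adjusted p = 0.18 with a preset correlation of 0.05, and adjusted p = 0.600 without genes holding AACAGCA). Over all genes tested 2 members fell and 1 rose, and adjusted over the list alone 3 fell and 1 rose. The secreted SCUBE3 and the transcription factor FOXF1 fell, with log2 values of −0.81 (SE 0.13) and −0.87 (SE 0.25), while SMO, the signal transducer of the pathway, rose by 0.89 (SE 0.24) in the authors' deposited table. In the TGF-beta target list (cameraPR adjusted p = 0.030, adjusted p = 0.18 with a preset correlation of 0.05, and adjusted p = 0.177 without genes holding AACAGCA) the latent TGF-beta binding protein LTBP1 fell by 0.53 (SE 0.08) in the authors' deposited table, the only call of 25 over all genes tested, and 2 fell adjusted over the list alone. By gene sums LTBP1, at −0.44 (SE 0.21), did not pass, and 0 members were called. The oxidative phosphorylation list passed (cameraPR adjusted p = 0.041, and adjusted p = 0.23 with a preset correlation of 0.05), but not without COX7C (cameraPR adjusted p = 0.66). COX7C rose by 2.14 (SE 0.11) and the complex II subunit SDHB fell by 0.23 (SE 0.07) in the authors' deposited table, the 2 of 41 members called over all genes tested and adjusted over the list alone.

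The RNA interference machinery list was lower under PRRX2 siRNA (cameraPR adjusted p = 0.0017) through 1 transcript of DICER1, the microRNA-processing nuclease, at −6.91 (SE 0.25) in the authors' deposited table. The DICER1 gene sum was at 0.55 (SE 0.55), the list median was −0.00 and the direction of the list turned without DICER1 (cameraPR adjusted p = 0.41). The Dicer partner TARBP2 and the Argonaute protein AGO4 rose by 1.74 (SE 0.41) and 0.96 (SE 0.26) in the authors' deposited table (the TARBP2 gene sum, 1.01 with an SE of 0.38, did not pass), so that 2 of 14 members were higher and 1 lower over all genes tested and adjusted over the list alone. In the unfolded protein response list (cameraPR adjusted p = 0.13) the chaperone-associated factor MANF and the chaperone CALR fell, with log2 values of −1.15 (SE 0.18) and −0.28 (SE 0.07) in the authors' deposited table, while the cochaperone DNAJB9 rose by 0.34 (SE 0.10). Adjusted over the list alone, 2 of its 23 members fell and 2 rose. In the hypoxia and glycolysis list (cameraPR adjusted p = 0.22) SLC2A3 rose by 0.52 (SE 0.11), and CA12 and the lactate dehydrogenase LDHA fell, with log2 values of −0.87 (SE 0.23) and −1.47 (SE 0.43) in the authors' deposited table, while the LDHA gene sum, −0.83 (SE 0.48), did not pass. Adjusted over the list alone, 1 of its 28 members rose and 2 fell. Markers of stromal fibroblasts (median −0.37, cameraPR adjusted p = 0.072), of pericytes and smooth muscle (−0.49, 0.13) and mitochondrially encoded transcripts (−0.10, 0.72) did not pass. The stromal fibroblast markers were however lower by ranks of the statistic (cameraPR adjusted p = 0.036) and by gene sums (cameraPR adjusted p = 0.0054), and the pericyte and smooth muscle markers by ranks of the statistic (cameraPR adjusted p = 0.038), beside the matrix and contractile genes.

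In the authors' deposited table, 387 transcripts rose and 420 fell under PRRX2 siRNA at a DESeq2 adjusted p under 0.05, and 2811 had an unadjusted p under 0.05. The lowest, an AMOTL2 transcript, went from an implied mean of 1652 to under the floor in the authors' deposited table, at least 1652-fold lower, while the AMOTL2 gene sum was at −0.08 (SE 0.36). The next lowest belonged to TNFRSF19, PTGES3, NT5C2, ZNF281, ARL13B, TMEM222, STX16, HNRNPAB and ZC3H6. The highest belonged to MAGED2, PPM1F, COPE, SUZ12, MATR3, STX16, ALG8, TNFRSF19, TDP1 and ARHGEF18. Of 666 genes with a called transcript and a gene sum, 222 had a gene sum that moved by less than 1.2-fold (33.3%).

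**Figure D2:**
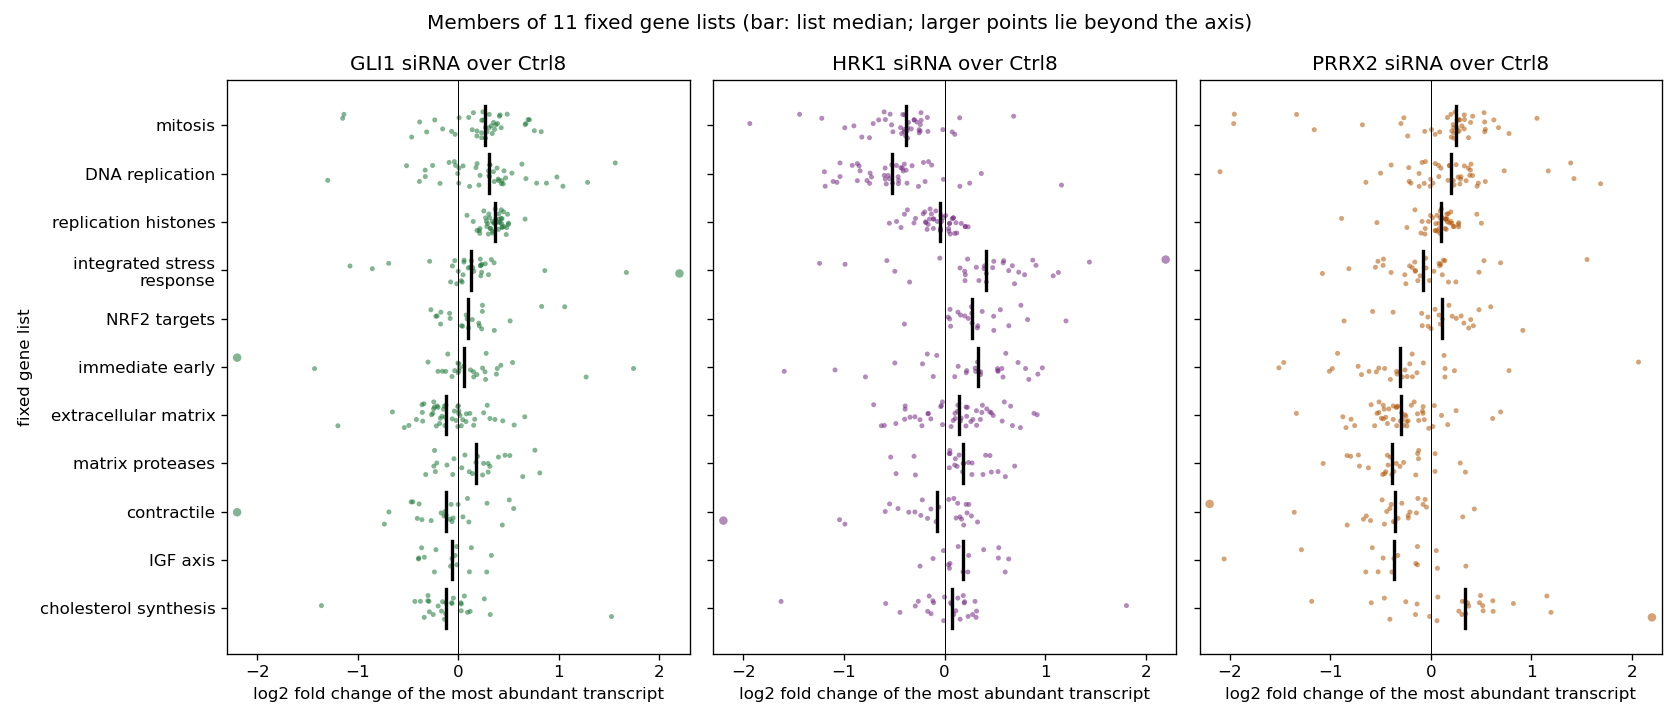
Log2 fold change of the most abundant transcript of each measured gene (horizontal axis) for 11 fixed gene lists (vertical axis) in the 3 comparisons. Each point is 1 gene, black bars are list medians, and larger points lie beyond the axis. Replication-dependent histones sit at a median of 0.37 under GLI1 siRNA and −0.04 under HRK1 siRNA, and DNA replication genes at 0.31 and −0.52.

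The siRNAs were then compared with each other by tests of the difference. Mitosis and DNA replication genes stood higher under GLI1 than under HRK1 siRNA (cameraPR on the z of the difference, adjusted p = 3.06e-12 and 5.84e-12), as did the replication-dependent histones (adjusted p = 1.67e-05). Mitosis and DNA replication genes did not differ past the test between GLI1 and PRRX2 siRNA (cameraPR adjusted p = 0.71 and 0.57). Both lists stood lower under HRK1 than under PRRX2 siRNA (cameraPR adjusted p = 1.08e-06 and 3.57e-07). Integrated stress response genes stood higher under HRK1 than under PRRX2 siRNA (cameraPR adjusted p = 7.18e-09) and than under GLI1 siRNA (cameraPR adjusted p = 0.00079). Immediate early genes stood higher under HRK1 than under PRRX2 siRNA (cameraPR adjusted p = 3.57e-07) and higher under GLI1 than under PRRX2 siRNA (cameraPR adjusted p = 3.59e-06). Extracellular matrix genes stood lower under PRRX2 than under HRK1 siRNA (cameraPR adjusted p = 2.17e-05) and than under GLI1 siRNA (cameraPR adjusted p = 0.020, and adjusted p = 0.20 with a preset correlation of 0.05). Cholesterol synthesis genes stood higher under PRRX2 than under GLI1 siRNA (cameraPR adjusted p = 0.00055) and than under HRK1 siRNA (cameraPR adjusted p = 0.018, and adjusted p = 0.12 with a preset correlation of 0.05).

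By single transcripts, 157 differed between GLI1 and HRK1 siRNA, 232 between GLI1 and PRRX2 siRNA and 196 between HRK1 and PRRX2 siRNA. The most different in the first pair were isoforms of SRPK1, RPL37A, SNX14 and MAP2K4, and the whole TOMM34 gene, which had a gene sum of −2.48 under GLI1 and −0.10 under HRK1 siRNA. SRPK1, MAGED2, ECHDC1, RPL37A and TOMM34 led the second pair, and ECHDC1 fell by 1.53 under PRRX2 siRNA. CCDC43, METTL7A, CDS2, NAXD and CCDC14 led the third. CDS2, an enzyme of phosphatidylinositol synthesis, fell, with log2 values of −0.55 (SE 0.16) under GLI1 and −0.68 (SE 0.13) under HRK1 siRNA, and rose by 0.53 (SE 0.06) under PRRX2 siRNA.

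Some transcripts were called in the same direction under more than 1 siRNA. GLI1 and HRK1 siRNA shared 50 transcripts higher in both and 50 lower in both, where independent lists would share 1.46 and 4.88. GLI1 and PRRX2 siRNA shared 50 and 43, against 2.37 and 5.48, and HRK1 and PRRX2 siRNA shared 44 and 41, against 2.38 and 6.07. Opposite calls numbered 0, 9 and 8. Those higher in the first and lower in the second were 0, 2 and 1, where independent lists would share 2.78, 3.19 and 3.36. Those the other way round were 0, 7 and 7, against 2.57, 4.07 and 4.30. All comparisons used the same control libraries, and simulated siRNA groups with no change shared a mean of 0.25, 0.28 and 0.22 calls. The control group had 3 libraries with no values of their own, so the controls could not be split, and part of the excess may come from them. The covariance of gene-sum log2 changes was 0.0521, 0.0599 and 0.0356, against 0.174, 0.174 and 0.175 in the simulation.

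In all 3 comparisons 34 transcripts were called, 17 higher throughout, 14 lower throughout and 3 with mixed signs. The lowest belonged to SUMF2, ACACA, CNEP1R1, PRR16 and GPRASP3, and the highest to PPM1F, RBM48, EPS8L2, UCHL3 and SGPL1. The PPM1F transcript lay under the floor with Ctrl8 and at 983, 1019 and 1256 implied normalised counts with GLI1, HRK1 and PRRX2 siRNA, while the PPM1F gene sum had values of 0.17, 0.39 and 0.12. The gene sums called in all 3 were those of SGPL1, KLHDC3, TTC19, CDS2 and MIB1. SGPL1, sphingosine-1-phosphate lyase, rose by 0.50 (SE 0.07) under GLI1, 0.59 (SE 0.16) under HRK1 and 0.58 (SE 0.08) under PRRX2 siRNA. KLHDC3, a substrate receptor of a ubiquitin ligase, rose by 0.39 (SE 0.09), 0.54 (SE 0.10) and 0.47 (SE 0.08), and TTC19, an assembly factor of respiratory complex III, by 0.31 (SE 0.08), 0.30 (SE 0.09) and 0.41 (SE 0.08). MIB1, a ubiquitin ligase of Notch signalling, fell, with log2 values of −0.46 (SE 0.07) and −0.23 (SE 0.07) under GLI1 and HRK1 siRNA and rose by 0.31 (SE 0.06) under PRRX2 siRNA.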

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

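The scan of 3' UTRs for 7-mers, the search for the 7-mer in the target transcripts, the test of unique 50-mers and the simulation of shared controls were planned before their outcomes were seen. The tests on gene sums, including the 14 tests of opposite movement given next, the count of words that share bases with the lowest, the test of risen genes and the covariance over genes with 1 dominant transcript were chosen after the data were seen.

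A group of genes had called gene sums that moved in opposite directions under different siRNAs, and the difference itself passed a two-sided Wald test on the z of the difference. Between GLI1 and PRRX2 siRNA, z was −8.55 for MIB1, at log2 values of −0.46 and 0.31, and −7.52 for PANK3, a pantothenate kinase of coenzyme A synthesis, at −0.30 and 0.50. CDS2 had a z of −6.49, with values of −0.55 and 0.53, and the lysosomal galactosylceramidase GALC one of −6.34, with values of −1.16 and 0.49. KLHL28 (z −5.98, from −0.34 and 0.49) and FAM234B (z −5.62, from −1.23 and 0.96) stood the same way round. The shedding protease ADAM17 (z 5.48, from 0.38 and −0.62) and the receptor phosphatase PTPRF (z 5.17, from 0.52 and −0.33) stood the other way round. Between HRK1 and PRRX2 siRNA, z was −8.71 for CDS2, at −0.68 and 0.53, −6.73 for DNAAF9, at −0.56 and 0.53, and −6.09 for ANKRD26, at −0.69 and 0.39. MIB1 had a z of −5.91 (−0.23 and 0.31), the deubiquitinase USP28 one of −5.41 (−0.52 and 0.48) and the early response gene IER2 one of 4.93 (0.61 and −0.40). These z values took the 2 estimates as independent although they share controls. The genes were picked as called with opposite signs, so a difference past the test follows almost from the choice and is no separate support.

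The first pattern weighed was the set of genes that fell under each siRNA. Carriers of 1 short 3' UTR word were lowest, with a z of −11.6 for GGTCCTG under GLI1, −15.0 for GAAGTCA under HRK1 and −9.22 for AACAGCA under PRRX2, where the lowest z over 100 shuffles was −4.96, −4.69 and −4.87, while in the other comparisons these words had a z between −1.42 and 0.63. Of the gene sums that fell 50%, 51.1% and 32.7% held the word and of those that rose 5.71%, 6.06% and 19.4%, against 1042, 1222 and 1459 of all 9386 genes searched, with no difference between risen genes and the others past a test (Fisher's exact test, two-sided, p = 0.424, 0.306 and 0.229). Each word was picked from these same gene sums, so its share among those that fell is no separate support. Below every shuffle lay 10, 10 and 28 words. Of these 9, 9 and 7, the lowest itself included, shared at least 5 bases in a row with the lowest. Under PRRX2 siRNA 21 did not, the lowest of them being CCCCTCC with a z of −7.41. Repression through the siRNA seed is thus a candidate explanation for part of the falls under GLI1 and HRK1 siRNA, PRDX3, SOD2, CTBP1 and LMAN1 being carriers, and a less specific one under PRRX2 siRNA, where an effect of other 3' UTR sequence stays open, as does loss of the targeted factor in all 3, which was not tested.

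The second pattern was the group of genes with transcripts called in opposite directions, 38 under GLI1, 32 under HRK1 and 50 under PRRX2 siRNA. If reads shared between near-identical isoforms were the cause, the called transcripts should hold fewer 50-mers of their own. The ratio of their median share of unique 50-mers to that of other transcripts of genes with several isoforms was 0.616 for GLI1, 0.359 for HRK1 and 0.749 for PRRX2. The bootstrap intervals, 0.432 to 1.03, 0.255 to 0.684 and 0.474 to 0.966, all included the bound of 0.5 set in advance. Shared reads and regulated splicing therefore cannot be told apart here, and the latter was not tested.

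The third pattern was movement in the same direction under different siRNAs. Simulated groups with the same controls and no change shared at most 3, 4 and 2 calls, against 100, 93 and 85 observed. These and the next values are for GLI1 and HRK1, GLI1 and PRRX2, and HRK1 and PRRX2 siRNA. With no change simulated, few adjusted calls could arise there, so this gap decides little. At an unadjusted p under 0.05 at most 104, 104 and 102 simulated transcripts were lower in both, against 209, 247 and 200 observed. At most 223, 225 and 240 were higher in both, against 243, 254 and 247 observed, a small excess. These unadjusted counts lay above the highest draw, but the simulation held no change under any siRNA. It also gave far more shared rises (means of 195, 193 and 193) than shared falls (81.0, 80.9 and 80.6), where the observed counts were closer. The unadjusted counts therefore do not decide how much of the sharing comes from shared control noise. The covariance of gene-sum changes, 0.0521, 0.0599 and 0.0356, lay below the lowest draw (0.153, 0.153 and 0.152), as did that of the statistic over genes with more than 90% of their counts in 1 transcript for GLI1 and HRK1 (0.327 against 0.473) and for HRK1 and PRRX2 (0.220 against 0.472) but not for GLI1 and PRRX2 (0.487 against 0.477), so that the simulation did not match the spread of these data, for a reason not tested, and the covariance decides nothing. Shared control noise, within or outside the simulated kind, stays open, as do common targets, which were not tested. Of the 34 transcripts called throughout, 5 were under the floor with Ctrl8 and higher with each siRNA. Ctrl8 was itself a transfected siRNA, so a response to transfected siRNA in general was in both arms. It could move transcripts here only where it was weaker or stronger than with Ctrl8, which was not tested.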

How the results depend on the processing

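The settings by gene sums, ranks of gene sums, all transcripts in place of 1 per gene, genes carrying the top 7-mer, GC content and length, and transcripts with an arm at the floor were chosen after seeing the data, and the others before the data were examined. No paired analysis was possible because the deposited tables hold no value per library. For the same reason leaving out each replicate, TMM, edgeR or a new DESeq2 fit and other splits of the 6 libraries were not run. The SE of single transcripts limits what low transcripts can show. The cause of the moves below was not tested unless the setting itself gives it.

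A stricter threshold or a larger error leaves fewer calls by construction. At an adjusted p under 0.01 the count of changed transcripts went from 639 to 408 for HRK1 and from 807 to 497 for PRRX2, and with an absolute log2 change of at least 1 to 496 for PRRX2. With the statistic divided by the root of 2, as if lanes had been entered as replicates, it was 195, 199 and 238 for GLI1, HRK1 and PRRX2, although the tables show that lanes had been merged. By gene sums 148, 185 and 320 genes changed, and the share of calls that were higher went from 47.4% to 26.4% for GLI1 and from 43.0% to 22.7% for HRK1, against 48.0% and 47.8% for PRRX2.

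Of the lists that passed, 3 for GLI1, 8 for HRK1 and 10 for PRRX2, a preset correlation of 0.05 left 1 for GLI1 and 5 for PRRX2. Gene sums gave 5 and ranks of gene sums 7 for GLI1. Without the strongest member 5 passed for HRK1. For PRRX2 all transcripts gave 4, and 6 passed without genes carrying the top 7-mer. The list median lay outside the central 95% of random lists, a criterion with no allowance for correlated genes, for 12, 14 and 19 lists. With the trend in GC content and length removed, 3, 8 and 7 of the lists still passed. The RNA interference list under PRRX2 siRNA turned from lower to higher by ranks of the statistic (adjusted p = 0.965), without DICER1 (0.408), by gene sums (0.320), by ranks of gene sums (0.449) and without genes carrying the 7-mer (0.400), and no other list that passed turned. Among lists that did not pass as planned, 2, 4 and 5 passed by gene sums, 4, 5 and 7 by ranks of gene sums and 0, 3 and 4 by ranks of the statistic, all in the direction of the planned test.

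Calls shared by GLI1 and HRK1, GLI1 and PRRX2, and HRK1 and PRRX2 siRNA went from 100, 93 and 85 to 61, 56 and 52 at an adjusted p under 0.01 and to 14, 21 and 18 by gene sums. Of the 20113, 20145 and 20107 transcripts tested in these pairs, 0.781%, 1.15% and 0.975% differed between the siRNAs. This share was 2.97%, 3.78% and 4.12% with a correlation of 0.5 between the estimates and 0.194%, 0.243% and 0.109% with the statistic divided by the root of 2. At an adjusted p under 0.01 it was 0.527%, 0.730% and 0.612%. By gene sums it was 0.653%, 1.10% and 0.907% of fewer units (11031, 11016 and 11025).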

Other observations

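The genes in the next paragraphs were chosen after their values were seen, and the test of microRNA sites was chosen after the result was seen, while the search of the target transcripts was planned.

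Under PRRX2 siRNA several genes outside the fixed rule fell by gene sum (two-sided gene-sum Wald tests with Benjamini-Hochberg adjustment). The collagen receptor subunit ITGA2 went from 2746 to 1201 normalised counts (log2 −1.19, SE 0.20, adjusted p = 1.92e-06). PAPSS2, which makes the sulfate donor for proteoglycans, went from 4843 to 2039 (log2 −1.25, SE 0.23), and the guidance ligand SLIT2 from 1288 to 678 (log2 −0.93, SE 0.15). The fibroblast surface protein THY1 had a log2 value of −0.59 (SE 0.16), the metallothionein MT2A −0.84 (SE 0.15) and SRF, a transcription factor of contractile genes, −0.57 (SE 0.10). TERT, whose cDNA was used to immortalise the line, went from 1853 to 815 (log2 −1.18, SE 0.35, adjusted p = 0.034). The retinoic acid receptor RARB rose from 32.7 to 94.8 (log2 1.54, SE 0.29), the Polycomb protein CBX7 by 1.27 (SE 0.25) and HMGCS1, of cholesterol synthesis, by 0.76 (SE 0.23).

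Under HRK1 siRNA CALD1, an actin-binding protein of smooth muscle and stroma, fell from 65710 to 31870 normalised counts (log2 −1.04, SE 0.20, adjusted p = 4.84e-05). The actin-disassembly factor WDR1 fell from 13887 to 8041 (log2 −0.79, SE 0.10), the actinin-binding protein PDLIM5 had a log2 value of −0.97 (SE 0.24), and the apoptosis inhibitor BCL2 one of −0.81 (SE 0.21). CALD1 and PDLIM5 held the 7-mer of this siRNA. The transcription factor IRF1 rose by 0.84 (SE 0.13), from 291 to 520. The heparan sulfate proteoglycan SDC4 fell under both HRK1 and PRRX2 siRNA, with log2 values of −0.90 (SE 0.19) and −1.08 (SE 0.16). The decidualization list, which holds genes of the hormone response of these cells, did not pass as planned under any siRNA, with medians of −0.21, 0.11 and −0.22 for GLI1, HRK1 and PRRX2 (cameraPR adjusted p = 0.20, 0.40 and 0.13). It was lower past the test under PRRX2 siRNA by gene sums (cameraPR adjusted p = 0.035) and ranks of gene sums (0.021), and under GLI1 siRNA by ranks of gene sums (0.019). PGR, the progesterone receptor, had gene-sum values of −0.50 (SE 0.18), −0.44 (SE 0.17) and 0.23 (SE 0.16), none past the test. Interferon response genes, which answer foreign RNA, did not pass either (cameraPR adjusted p = 0.74, 0.29 and 0.72), with transfected siRNA in both arms of each comparison.

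If the 7-mer is the seed match of the siRNA, the targeted transcript should hold it. The GLI1 transcript held 2 copies of GGTCCTG and the PRRX2 transcript 2 copies of AACAGCA, where 28.2% and 14.9% of transcripts of like length held at least 1. These counts are consistent with the seed match as a candidate explanation, which the 21 other words under PRRX2 siRNA make less specific there, but the siRNA sequences were not used here, and the HRK1 target could not be searched because its identity is open.

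A second hypothesis was that transfected siRNA competes with endogenous microRNAs for Argonaute, so that microRNA targets rise. Over 7-mer sites of 16 microRNAs common in fibroblasts the mean z was 1.47, 1.90 and 1.69 for GLI1, HRK1 and PRRX2, against 0.11, 0.48 and −1.28 over sites of 7 tissue-restricted microRNAs. The exact permutation p was 0.0926, 0.0162 and 0.000506 (Benjamini-Hochberg adjusted 0.0926, 0.0243 and 0.00152). The site of miR-17, GCACTTT, had already been seen as the highest word under PRRX2 siRNA, and without it the exact permutation p was 0.126, 0.0180 and 0.000727. Of the 16 sites 13, 15 and 13 had a z above 0. The site of miR-29 had a z of 3.49, 3.90 and 3.20, while that of miR-31 went the other way at −3.32, −0.72 and −1.09, as did that of miR-143 for GLI1 and PRRX2 at −1.50 and −1.39. The difference had the predicted sign in all 3 comparisons but passed in 2, and the sites differ in base composition. So do the genes that moved (Spearman correlation of the most abundant transcript's statistic with its GC content −0.07, 0.22 and −0.18 across genes, which are not independent replicates). The z of the sites had trends in 3' UTR length and GC content removed, so these correlations do not show what effect of composition remains in it. How far each siRNA and Ctrl8 compete was not measured, so whether release of microRNA targets contributes to the genes that rose stays undecided. An effect of composition was not excluded.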
